A study of Bagarius yarrelli and Glyptothorax macromaculatus and Oreoglanis setiger with 27 samples.

How the data were processed

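Total RNA was extracted with TRIzol and treated with DNase I, and libraries were prepared with an Illumina TruSeq RNA kit, per the labels' protocols. Bowtie2, RSEM and the zebrafish genome build Zv9 are named in the submitters' processing notes, without versions or roles. The file names call the deposited values normalised counts. How the authors normalised them, which genes they kept and whether the 3 tables were scaled together is not given in the sources used here.

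Samples were placed in groups from their titles, which give the species code, a number read here as the individual, and the tissue. The 27 value columns of the deposited tables, 9 per table, carry only running numbers as names, per the file headers. Each file name carries a species code, but no label pairs the column names with samples, so all 27 were left unassigned and their values entered no result. The depth of each library, the spread between individuals and every planned limma comparison are therefore not reported here.

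The gene symbol column was read from each table with Python 3.11.15. Symbols were compared between tables as written. They were matched without regard to case to 20 gene lists with named members and 3 lists given as symbol patterns, all fixed before the data were examined. A gene in several lists was counted in each. The rule fixed for naming genes needed expression tests, so the genes named were instead chosen as familiar members of each list, after it was seen which ones were listed. A looser match that ignored a final a or b on both sides (for symbols of more than 3 characters), chosen after seeing the data, is given beside the exact one. No gene coordinates were used, since no reference annotation was used here.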

Results

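Transcriptomes were collected from 3 sisorid catfish species, Bagarius yarrelli, Glyptothorax macromaculatus and Oreoglanis setiger. Brain, liver and muscle samples share a number in their titles, which was read as the fish they came from. On that reading, 3 individuals were sampled per species. The 27 samples therefore form 9 groups of 3, with 9 samples per species and 9 per tissue. The series title names the evolution of body size as its subject, and Bagarius yarrelli is known as the large-bodied species among them. The design implies comparisons of the 3 tissues within each species, of the 3 species within each tissue, and of tissue differences between species.

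None of these expression comparisons could be made here. The values stand in 3 tables of 9 columns each, whose headers give the 27 columns only running numbers. These numbers match no sample label, so no column could be tied to a tissue or an individual. Column order and the values themselves were not used as a substitute, and no expression level, fold change or library depth is reported. Each table is named for a single species, but a name of this kind does not tie a column to a sample, and species differences pooled over unknown tissues were not examined. The genes that the tables list are described here instead.

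Each table listed 9509 gene symbols, and all 3 held the same symbols in the same order, with 0 symbols repeated. Of these, 393 (4.13%) were clone-style or database identifiers in place of a descriptive name. The rest mix zebrafish-style symbols with suffix-free ones, such as ghra beside ghr and ldb3b beside ldb3. In 220 cases a pair of listed symbols of more than 3 characters differed only in a final a or b, leaving aside symbols with a colon. Such pairs include zebrafish duplicates (plp1a and plp1b) and distinct genes whose names end that way (cd79a and cd79b). Of the 20 gene lists with named members fixed before the data were examined, 328 of 904 memberships (36.3%) were found by exact symbol and 473 (52.3%) when a final a or b was ignored. Both counts are given for each list, since the looser one also credits a member when only a similarly named gene is listed, and still misses some members listed under another form. Under the looser match a single listed symbol can credit both members of a pair, as igf2 does for igf2a and igf2b. The counts and shares describe names. A listed symbol does not show that the gene was expressed in any sample, and an unlisted one does not show that it was unexpressed.

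Growth signalling genes were listed in part. Of the growth hormone and insulin-like growth factor axis, 12 of 54 symbols were listed exactly and 36 when a final a or b was ignored. The exact matches included igf1, the circulating growth factor made mainly by liver, ghra, a growth hormone receptor, igfals, which stabilises IGF complexes in blood, and the binding proteins igfbp1a, igfbp2a, igfbp3 and igfbp7. The growth factor igf2, its receptor kinase igf1r and the insulin receptor insr were listed without a suffix. Members found under neither rule included gh1, the symbol for growth hormone, and jak2a, jak2b, stat5a and stat5b. Other forms of these names were not searched for. Of the mTOR pathway, which couples nutrients and growth factors to protein synthesis, 31 of 65 symbols were listed exactly and 40 under the looser match. They included the kinase mtor, its partner rptor, the activator rheb and the translation repressor eif4ebp1. Of the Hippo pathway and growth arrest list, 19 of 42 symbols were listed exactly and 25 under the looser match, including the coactivators yap1 and wwtr1, the kinases lats1 and lats2, and the tumour suppressor rb1. Of the regulators of muscle growth, 18 of 48 symbols were listed exactly and 27 under the looser match. They included mstnb, a myostatin that restrains muscle mass, its antagonist fsta, the myogenic factor myog and the atrophy-associated ubiquitin ligases fbxo32, trim63a and trim63b.

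The coverage of tissue markers depended on how symbols were matched. It changed more for the neuronal and muscle lists than for the hepatocyte, egg yolk and glia lists. Of the hepatocyte list, 42 of 87 symbols (48.3%) were found exactly and 49 (56.3%) when a final a or b was ignored. They included the fatty acid binding protein fabp10a, the fibrinogen chains fga, fgb and fgg, and cyp7a1, the rate-limiting enzyme of bile acid synthesis. The list of egg yolk genes of liver, with some egg coat genes, had 5 of 17 exactly and 6 under the looser match, including the yolk precursors vtg1 and vtg3, which liver makes, and the oestrogen receptor esr1. Of the neuronal list, 18 of 84 (21.4%) were found exactly and 42 (50.0%) under the looser match, including the synaptic genes snap25a and snap25b and the GABA-synthesising enzymes gad1b and gad2. Of the glia and myelin list, 16 of 39 were found exactly and 18 under the looser match, including mbpb, plp1a, plp1b and gfap. Of the muscle contractile list, 13 of 69 (18.8%) were found exactly and 25 (36.2%) under the looser match. They included the myosin light chain mylpfa, the Z-disc genes tcap and ldb3b and, without a suffix, the muscle creatine kinase ckm. Many core members were found under neither rule, among them the actins acta1a, acta1b, actc1a and actc1b. The myosin heavy chains myha, myhb and myhz2 were also missing, as were neb, ryr1a, ryr1b and atp2a1. Other forms of these contractile gene names were not searched for. Of the slow and oxidative muscle list, 4 of 25 were found exactly, namely mb (myoglobin), ppargc1b, sox6 and tnnt1, and 11 under the looser match.

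Lists of markers of other cell types were matched in the same way. A listed symbol does not show that such cells were in the samples. The erythrocyte list had 8 of 27 symbols exactly and 9 under the looser match, with the haem synthesis genes alas2, urod and uros among them. The leukocyte list had 11 of 41 exactly and 20 under the looser match, including the B cell genes cd79a and cd79b. The pancreatic acinar list had 5 of 29 under both rules, including ela2 and cpb1. The pituitary hormone list had 4 of 13 exactly, namely fshb, lhb, pomca and prl, and 5 under the looser match. The extracellular matrix list had 15 of 54 exactly and 27 under the looser match, including col2a1a, sparc and mmp2.

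Of the cell cycle list, 27 of 41 symbols (65.9%) were listed exactly and 29 (70.7%) when a final a or b was ignored, including pcna, cdk1 and the replication helicase subunits mcm2, mcm4, mcm5, mcm6 and mcm7. Glycolysis had 15 of 28 exactly and 20 (71.4%) under the looser match. The hypoxia response list had 25 of 47 and 30, and lipid metabolism had 23 of 49 and 28, including fasn, the fatty acid synthase. The immediate early and heat shock list had 17 of 45 exactly and 21 under the looser match. The symbol pattern for ribosomal proteins matched 51 symbols, and that for oxidative phosphorylation subunits and assembly factors matched 65. The proteasome pattern matched 44. The patterns also caught symbols outside these classes, such as rps19bp1, a binding partner of a ribosomal protein, and psmc3ip, a meiotic recombination factor.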

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

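No paired analysis was possible because the value columns carry no replicate number, tissue or individual. None of the alternatives planned for the expression comparisons was run, for the same reason: other pseudocounts, filters and scalings, leaving out each library, and the individual fish as a block. One alternative for matching symbols was chosen after seeing the data. When a final a or b was ignored, 473 of 904 list memberships (52.3%) were matched, against 328 by exact symbol. The move was largest in share for the growth hormone and insulin-like growth factor axis, from 12 to 36 of 54 (22.2% to 66.7%). Many members of that list are a and b pairs, and a single listed symbol such as igf2 credited both members. The pancreatic acinar list did not move, at 5 of 29. The looser match also counts a member when only a similarly named gene is listed, as for igfbp1b beside igfbp1a, and it misses a member whose listed form loses its own last letter, as for mef2aa beside mef2a. It is therefore not an upper limit.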
